A study of Mus musculus with 10 samples.

How the data were processed

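The study measured RNA from primary mouse hepatocytes by poly-A selected RNA sequencing. The hepatocytes came from wild-type mice and were exposed overnight to conditioned medium from cultured adipocytes. The adipocytes were differentiated from the stromal vascular fraction of inguinal fat of male mice that had been on an obesogenic diet for 6 months. The fat donors either carried floxed Mttp alleles or lacked Mttp in adipose tissue, and the labels give 3 donor mice. Mttp encodes the microsomal triglyceride transfer protein, which loads lipid onto apolipoprotein B in cells that secrete lipoproteins. The group that received medium from floxed adipocytes is called Mttp_flox_CM and the group that received medium from knockout adipocytes Mttp_KO_CM, with 5 libraries each.

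The authors deposited a table of counts per gene, 1 column per library, and the values are whole numbers. They also deposited a table of FPKM values for the same libraries. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used, with genome build GRCm39. The strand setting, the treatment of reads that match several genes and the annotation release are not given in the sources used here. The labels' library protocol describes second-strand synthesis with dTTP, so the counts were treated as unstranded. Each deposited FPKM value equalled the count divided by the gene length and by 1 constant per library. The summed counts were 0.982 ± 0.00138 (SD, n = 5) of the library size implied by that constant in Mttp_flox_CM and 1.01 ± 0.00375 in Mttp_KO_CM. The FPKM values therefore carried a scaling between libraries that the sources used here do not describe.

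Column names in both tables matched the labels for 8 libraries. The other 2 columns, 1 per group, carried a number that no label gives. Their letter put them in a group, so they were used as replicates without a number, called the unnumbered libraries, and the counts of genes higher and lower, the single genes and the list tests were repeated without them. All 10 columns were used.

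Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 14183 of 56748 genes and 99.8% of the counts. Libraries were scaled by TMM (trimmed mean of M values), with factors of 1.01 ± 0.00187 in Mttp_flox_CM and 0.986 ± 0.00447 in Mttp_KO_CM. A quasi-likelihood model with 1 term for the group was fitted and tested with glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 counted as a change. Expression is given as CPM, the count scaled in the usual way by the library size, here TMM-scaled, as mean ± SD over 5 libraries, and log2 fold changes are Mttp_KO_CM over Mttp_flox_CM with their standard errors (SE). Fitted fold changes use a prior count of 0.125, which affects genes with few counts. Nothing in the labels says that the 5 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

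Before the data were examined, 37 gene lists were written down. They covered PPARα targets, mitochondrial and peroxisomal fatty acid oxidation, ketone body synthesis, fatty acid omega hydroxylation, lipid droplet proteins, fatty acid and triglyceride synthesis, cholesterol synthesis, lipoprotein assembly, bile acids, gluconeogenesis, glycolysis and oxidative phosphorylation. Further lists held the mitochondrially encoded genes, PPARγ-linked steatosis genes, stress and inflammatory responses, NRF2, hypoxia, circadian and glucocorticoid genes, drug metabolism, cell cycle, matrix, immediate early genes and ribosomal proteins. Marker lists covered hepatocytes, progenitor-like cells, macrophages, stellate cells, endothelial cells, cholangiocytes, lymphocytes with neutrophils, adipocytes and red blood cells. Of the listed symbols, 11 were matched through an older or newer symbol. Lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 36 lists with at least 2 genes tested. The counts of a list's members are given over all genes tested and, where they differ, adjusted over the list alone.

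Named genes followed a rule written before the data were examined. It took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean CPM of at least 5 and a gene symbol rather than a clone name. It added up to 8 PPARα targets and up to 4 members of every other list with the smallest p-values, and 15 genes of hepatic lipid metabolism. Not every gene that the rule takes is given in the text. Members named because they went against their list, and the genes Txnip, Gm15441, Xist, Cxcl2, Cxcl10, Apob, Slc2a2 and Acnat2, were chosen after their values were seen.

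The alternatives tried were DESeq2 size factors, upper-quartile factors and library size alone, no filter and a stricter filter (10 counts in 5 libraries and a mean CPM of 1), DESeq2 1.42.0, limma-voom with and without sample weights, limma on log2 of FPKM plus 1 or plus 0.1 (FPKM of at least 0.5 in 5 libraries, or no filter), a block on replicate number, 1 surrogate variable (sva 3.50.0), protein-coding genes alone, an adjusted p under 0.01, a fold change of at least 1.5, and each library left out in turn. Robust estimation in edgeR, the counts without the unnumbered libraries, and lists without their PPARα targets were added after seeing the data. On simulated counts with these library sizes and means, edgeR recovered 60% of 50 genes changed 1.25-fold, 76% at 1.5-fold, 86% at 2-fold and 94% at 4-fold, and called 12 of 13983 unchanged genes. Camera called 0 of 200 simulated lists without a change. The simulated genes were drawn independently, so this does not cover lists whose genes vary together, such as the PPARα targets (estimated correlation 0.22). Far fewer genes were changed in the simulation than were called in the data. The adjustment over genes was therefore stricter there, and the recovery does not give the power of the real comparison.

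Gene coordinates are those in the authors' table. The reference annotation at hand is of another build and was used for gene symbols and GC content alone. Near-identical genes such as Acot1 to Acot4, the Cyp4a family, Acaa1a with Acaa1b and the Serpina1 genes can share reads, so their individual values are uncertain. The same holds for genes that overlap on opposite strands. Among the named genes these are G0s2 and Lamb3, Lamb3 and Hsd11b1, Txnip and Gm15441, Acot3 and 4732463B04Rik, Gpr182 and Zbtb39, Eng and Fpgs, Srebf1 and Rai1, Ndufs1 and Eef1b2, Ccnd1 and LTO1, Plin4 and Hdgfl2, Cxcl10 and Art3, Pfkfb1 and Apex2, Fitm1 and Gm15932, and Echs1 and Paox. The pairs mt-Co3 with mt-Atp6 and Serpina1b with Serpina1d each overlap on 1 strand.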

Results

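RNA-seq libraries of cultured wild-type mouse hepatocytes were compared, 5 from cells given medium of Mttp-floxed adipocytes (Mttp_flox_CM) and 5 from cells given medium of Mttp-knockout adipocytes (Mttp_KO_CM). Summed counts per library ran from 14199798 to 15950530 in Mttp_flox_CM and from 14283517 to 17178131 in Mttp_KO_CM. Counts above 0 were found for 21667 ± 187 (SD, n = 5) and 21586 ± 243 genes. The 10 genes with the most counts took 10.6 ± 0.144% of counts in Mttp_flox_CM and 9.51 ± 0.0722% in Mttp_KO_CM. Genes of the mitochondrial genome took 3.42 ± 0.0524% and 3.54 ± 0.0803%. The title of the series names hepatic steatosis and PPARα activity, and the comparison asks how hepatocyte transcripts differ between the 2 media.

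Mttp itself was expressed in every library, since the deletion was in the fat donors and not in the hepatocytes. Its level was 561 ± 17.1 CPM (SD, n = 5) in Mttp_flox_CM and 846 ± 20.1 CPM in Mttp_KO_CM. It rose by 0.59 on the log2 scale (SE 0.026, edgeR adjusted p = 3.0e-15), with every Mttp_KO_CM library above every Mttp_flox_CM library. Mttp (ENSMUSG00000028158) lies on chromosome 3 from 137795615 to 137850729 on the minus strand (GRCm39). The level in hepatocytes does not test the label of the medium. Without the unnumbered libraries, an alternative added after seeing the data, the log2 change was 0.60.

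In cultures given knockout medium, PPARα targets and genes of fatty acid oxidation were higher, and genes that mark liver endothelial and stellate cells were lower. Among 14183 genes tested, 2585 were higher and 2571 lower in Mttp_KO_CM (edgeR, adjusted p under 0.05). Most of these changes were small, and 79.4% of the called genes differed by less than 1.5-fold. At 1.5-fold or more there were 344 genes higher and 716 lower, and at 2-fold or more 150 higher and 202 lower. Values of the 2 groups did not overlap for 25.7% of genes tested, where chance gives 0.794%. The first principal component carried 45.9% of the variance. The share of called genes that were higher was 50.1% with TMM scaling and 38.1% with library size alone. Without the unnumbered libraries 2264 genes were higher and 2307 lower. Genes named below because they went against their list were chosen after their values were seen. Among them the calls for Lpin1, Gstm3, Rsad2, Mcm6, Cd68, Ccn1 and Tubb2b were each lost under at least 1 alternative. Lpin1 lost its call under 16 of 25 alternatives, Ccn1 under 14 and Rsad2 under 13.

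The 12 largest rises began with the acyl-CoA thioesterases Acot3 and Acot1. Acot1, a cytosolic acyl-CoA thioesterase (ENSMUSG00000072949, chromosome 12 from 84056264 to 84065145, plus strand), went from 23.6 ± 3.45 to 468 ± 15.7 CPM (log2 4.31, SE 0.057, edgeR adjusted p = 9.2e-26). Its mitochondrial neighbour Acot2 rose 8.24-fold. Acot3 had between 1 and 5 counts in each Mttp_flox_CM library and between 259 and 410 in each Mttp_KO_CM library, or 0.169 ± 0.114 and 21.6 ± 2.88 CPM. Its fitted log2 change of 6.92 depends on the prior count and ran from 2.78 to 7.25 over the alternatives. Fabp1, the liver fatty acid binding protein, rose from 21.9 ± 3.59 to 323 ± 26.7 CPM. The microsomal fatty acid hydroxylases Cyp4a14 and Cyp4a10 rose 13.4-fold and 10.7-fold. Pdk4, a kinase that turns off pyruvate dehydrogenase, rose from 222 ± 20.7 to 1429 ± 33.6 CPM (log2 2.68, SE 0.043). G0s2, an inhibitor of adipose triglyceride lipase, rose 8.23-fold, and Fbp2, a fructose bisphosphatase, 13.1-fold. The mitochondrial carrier Slc25a34 (log2 2.67), the laminin chain gene Lamb3 (log2 2.53) and the acetylcholine receptor gene Chrna2 (log2 2.41) completed the set. Lamb3 overlaps G0s2 on the opposite strand, and G0s2 had 5.48 times its counts, so its own change was not separated from that of G0s2.

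**Figure D1:**
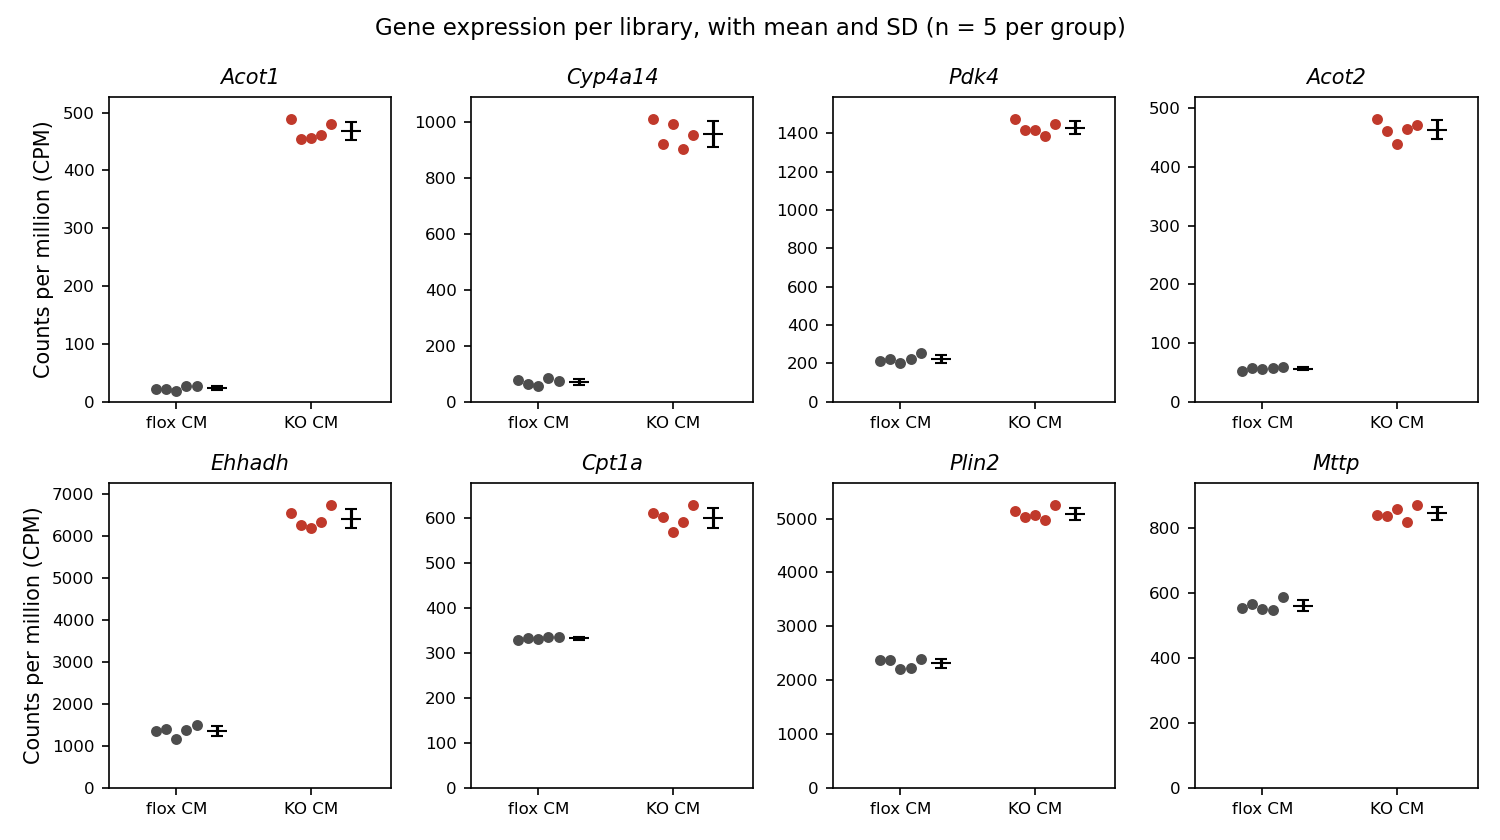
CPM of 8 genes in each of the 10 libraries (points), with the group mean and SD beside them (n = 5 per group); the y axes start at 0. All Mttp_KO_CM libraries lie above all Mttp_flox_CM libraries for each gene, from Mttp (561 and 846 CPM) to Acot1 (23.6 and 468 CPM).

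Known PPARα targets rose almost without exception. Of 43 tested, 42 rose and 0 fell, and the remaining gene, Fitm1, had a log2 change of 0.14 (SE 0.24). The median log2 change was 1.13 (camera adjusted p = 1.2e-65, and adjusted p = 0.0072 with an estimated correlation). Ehhadh, the peroxisomal bifunctional enzyme, rose from 1354 ± 127 to 6400 ± 223 CPM, Acsl1, which activates long-chain fatty acids, rose 4.06-fold, and Retsat, a retinol saturase, rose 4.05-fold. Ppara itself rose less, from 56.1 ± 3.35 to 70.8 ± 6.5 CPM (log2 0.33, SE 0.055, edgeR adjusted p = 2.9e-05). The hepatokine gene Fgf21 stayed at a low level, 2.06 ± 0.37 and 3.62 ± 0.62 CPM (log2 0.81, SE 0.18), and Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 0.67. The fatty acid transporter Cd36 rose by 0.81.

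Mitochondrial fatty acid oxidation rose in 21 of 24 genes, 0 fell, and adjusted over the list alone 22 rose (median log2 0.82, camera adjusted p = 6.0e-27). Cpt1a, which admits long-chain fatty acids to mitochondria, rose from 333 ± 3.03 to 601 ± 22.2 CPM (log2 0.85, SE 0.027). The trifunctional protein subunits Hadha and Hadhb rose by 1.05 and 1.01, while Echs1 showed 0.00 (SE 0.037). Peroxisomal oxidation rose in 16 of 20 genes and fell in 1, and adjusted over the list alone in 17 with 2 lower (median log2 0.48, camera adjusted p = 1.2e-14). Pex11a, which drives peroxisome division, rose by 1.77 and the fatty acid importer Abcd3 by 1.39. Ketone body genes rose in 6 of 7 and fell in 1. The ketone exporter Slc16a1 rose by 0.71, Acat1 by 0.61 and Bdh1 by 0.54, and Slc16a7 fell by 0.18 (median log2 0.54, camera adjusted p = 2.1e-06). Omega hydroxylation genes rose in 7 of 11, and adjusted over the list alone 7 rose and 2 fell. Cyp4a31 rose by 1.79 and the fatty aldehyde dehydrogenase Aldh3a2 by 0.71 (median log2 0.71, camera adjusted p = 5.6e-07). These lists share members with the PPARα targets, 12 in mitochondrial oxidation, 6 in peroxisomal oxidation, 1 in ketone bodies and 4 in omega hydroxylation. With the shared members left out, chosen after seeing the data, the medians were 0.36, 0.37, 0.41 and 0.08, and omega hydroxylation no longer passed (camera adjusted p = 0.112). With an estimated correlation these 4 lists had adjusted p = 0.0080, 0.021, 0.020 and 0.021.

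Genes of lipid storage and synthesis also rose. Among lipid droplet proteins 13 of 20 rose and 2 fell (median log2 0.48, camera adjusted p = 1.2e-09, and adjusted p = 0.010 with an estimated correlation). The droplet median was 0.22 and 0.31 without Mttp_flox_CM replicate 2 or 3, 0.21 and 0.19 without Mttp_KO_CM replicate 3 or the unnumbered one, 0.31 without both unnumbered libraries and 0.21 without its 4 PPARα targets. Plin2, the main coat protein of hepatocyte droplets, rose from 2312 ± 84.6 to 5086 ± 109 CPM (log2 1.14, SE 0.026). Hsd17b11 rose by 1.33 and the monoglyceride lipase Mgll by 1.38, while Plin3 fell by 0.21 and Plin4 by 0.35. Fatty acid and triglyceride synthesis rose in 19 of 23 genes and fell in 2, Scd2 and Lpin1, and adjusted over the list alone 20 rose (median log2 0.24, camera adjusted p = 1.3e-11, and adjusted p = 0.020 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, rose from 643 ± 13.2 to 1690 ± 120 CPM (log2 1.40, SE 0.036). The lipogenic regulator Srebf1 rose by 0.72, Acacb by 0.94, the acyltransferases Gpam and Dgat2 by 0.76 and 0.72, and Fasn, the fatty acid synthase, by 0.22 (SE 0.037). Scd2 fell by 0.38 and Lpin1 by 0.16. The PPARγ-linked steatosis genes rose in 9 of 14 and fell in 3 (median log2 0.38, camera adjusted p = 7.6e-04), but not with an estimated correlation (adjusted p = 0.098), and the median was 0.17 without its 2 PPARα targets, 0.23 without the unnumbered libraries or with a block on replicate number, 0.21 with the stricter filter and 0.20 on log2 of FPKM plus 1. Cidec, a droplet fusion protein, rose by 1.38, the uncoupling protein gene Ucp2 by 1.14 and the glycerol kinase Gk by 0.56. The 3 that fell were Pparg itself, by 0.72, Lpl by 0.51 and Plin4.

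**Figure D2:**
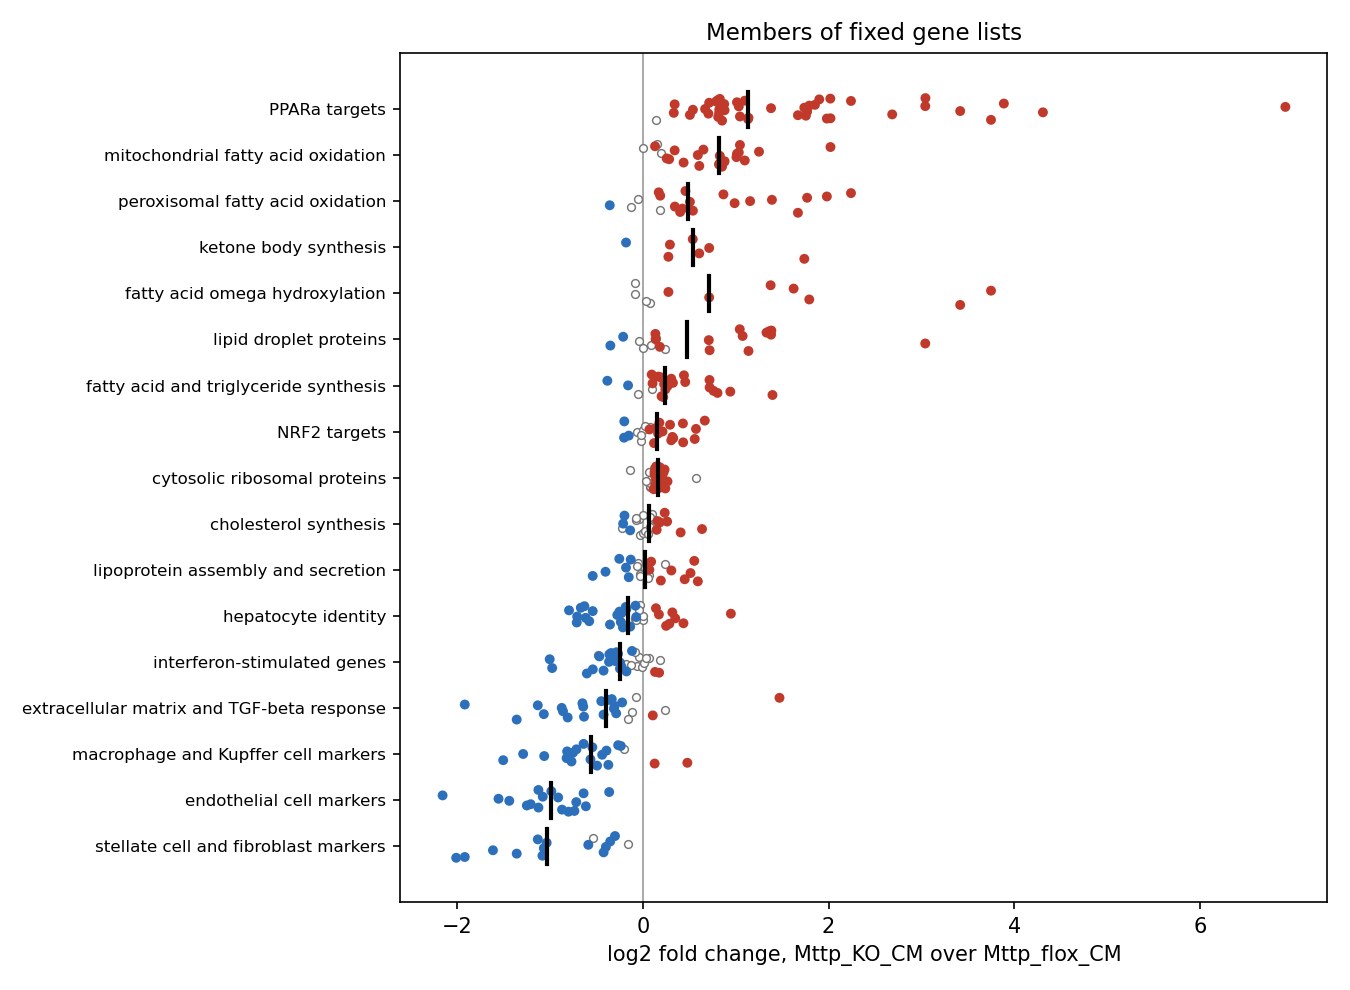
Log2 fold change of each tested member (points) of 17 gene lists, Mttp_KO_CM over Mttp_flox_CM, with the list median as a black bar; red and blue points passed the edgeR threshold as higher or lower and open points did not. The PPARα targets lie at a median of 1.13 and the endothelial and stellate markers at medians of -0.99 and -1.04.

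Other metabolic lists moved little as groups. Cholesterol synthesis had 7 of 24 genes higher and 3 lower (median log2 0.07, camera adjusted p = 0.136, but 0.0306 without Mttp_KO_CM replicate 4, 0.0420 without the unnumbered Mttp_KO_CM library, 0.0445 with no filter and 0.0331 with a block on replicate number), with Hsd17b7 up by 0.64 and Dhcr7 by 0.41, and Sc5d down (log2 -0.21). Lipoprotein assembly genes split, with 8 of 24 higher and 6 lower (median log2 0.02, camera adjusted p = 0.47). Apob, the structural protein of very low density lipoprotein, was at 7358 ± 137 and 7355 ± 333 CPM (log2 0.00, SE 0.027), while Apoa1 fell by 0.54. The secretory GTPase gene Sar1b and the cholesterol exporter Abca1 rose by 0.55 and 0.51. Bile acid genes had 5 of 14 higher and 4 lower, with Abcc2 up by 0.41 and the bile salt export pump Abcb11 down (log2 -0.45), and the median of 0.06 and the mean of -0.05 differed in sign, the test following the median (camera adjusted p = 0.973). Gluconeogenesis had 5 of 16 genes higher and 5 lower, and adjusted over the list alone 7 and 5. Its median of -0.02 and mean of 0.07 differed in sign, the test following the mean (camera adjusted p = 0.703), with Creb3l3, a fasting-induced transcription factor, up by 1.90, G6pc by 0.79, and Tat and Igfbp1 down (log2 -0.97 and -0.28). Glycolysis rose in 12 of 22 genes and fell in 3, Pfkfb1, Pfkfb3 and the glucose transporter Slc2a2, and adjusted over the list alone 13 rose and 4 fell (median log2 0.21, camera adjusted p = 7.6e-04). Pkm rose by 0.47 and Eno1 by 0.29, but the list did not pass with an estimated correlation (adjusted p = 0.29), and Mttp_flox_CM replicate 4 stood apart with a mean log2 CPM of 6.42 where the others averaged 6.18. Nuclear oxidative phosphorylation genes rose in 12 of 32, adjusted over the list alone in 13, and 0 fell, with Cycs, the cytochrome c gene, up by 0.39 (median log2 0.09, camera adjusted p = 1.3e-04, and adjusted p = 0.14 with an estimated correlation). Mitochondrially encoded genes rose in 8 of 12, adjusted over the list alone in 10, with mt-Cytb up by 0.24 (median log2 0.18, camera adjusted p = 8.1e-05, and adjusted p = 0.098 with an estimated correlation).

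Most markers of endothelial cells, stellate cells and macrophages fell. All 17 endothelial markers fell (median log2 -0.99, camera adjusted p = 8.9e-28, and adjusted p = 0.0080 with an estimated correlation). Kdr, a VEGF receptor, went from 122 ± 5.50 to 44.9 ± 2.07 CPM (log2 -1.44, SE 0.042), the TGF-beta co-receptor Eng fell by 1.12, the sinusoidal receptor Fcgr2b by 1.21 and Gpr182 by 1.55. Of 15 stellate cell and fibroblast markers 13 fell, adjusted over the list alone 14, and 0 rose (median log2 -1.04, camera adjusted p = 3.9e-09, and adjusted p = 0.0080 with an estimated correlation). Lrat, which stores retinol as ester, fell by 2.01, the smooth muscle actin gene Acta2 by 1.92 and the collagen genes Col1a1 and Col3a1 by 1.36 and 1.07, with mean values under 20 CPM for each. On log2 of FPKM plus 1 the stellate median was -0.41. Macrophage markers fell in 17 of 20 (median log2 -0.55, camera adjusted p = 1.3e-09, and adjusted p = 0.033 with an estimated correlation). The scavenger receptor Cd163 fell by 1.06, Vsig4 and C1qa by 0.82 each, while Cd14 rose by 0.48 and Cd68 by 0.13. Matrix and TGF-beta genes, 4 of which are also stellate markers, fell in 18 of 24 (median log2 -0.39, camera adjusted p = 5.5e-10, and adjusted p = 0.0091 with an estimated correlation). Fn1, the fibronectin gene, fell by 0.65, Sparc by 0.63 and Spp1 by 0.86, and among the 2 genes that rose Ccn1 did so by 0.11.

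The 12 largest falls included Gpr182 of the endothelial list. The others were on none of the lists tested, and comprised Clec14a and Clec1a, lectins of endothelium, the endothelial transcription factor Sox18, the cadherin Pcdh12, the lipoprotein lipase anchor Gpihbp1, the water channel Aqp1, and Slco1a4, Abcc9, Prelp, C1qtnf1 and Armcx4. The 12 log2 changes lay between -2.02 for C1qtnf1 (13.1 ± 1.38 to 3.21 ± 0.877 CPM) and -1.48 for Pcdh12, and Aqp1 went from 70.2 ± 4.15 to 20.7 ± 1.33 CPM.

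**Figure D3:**
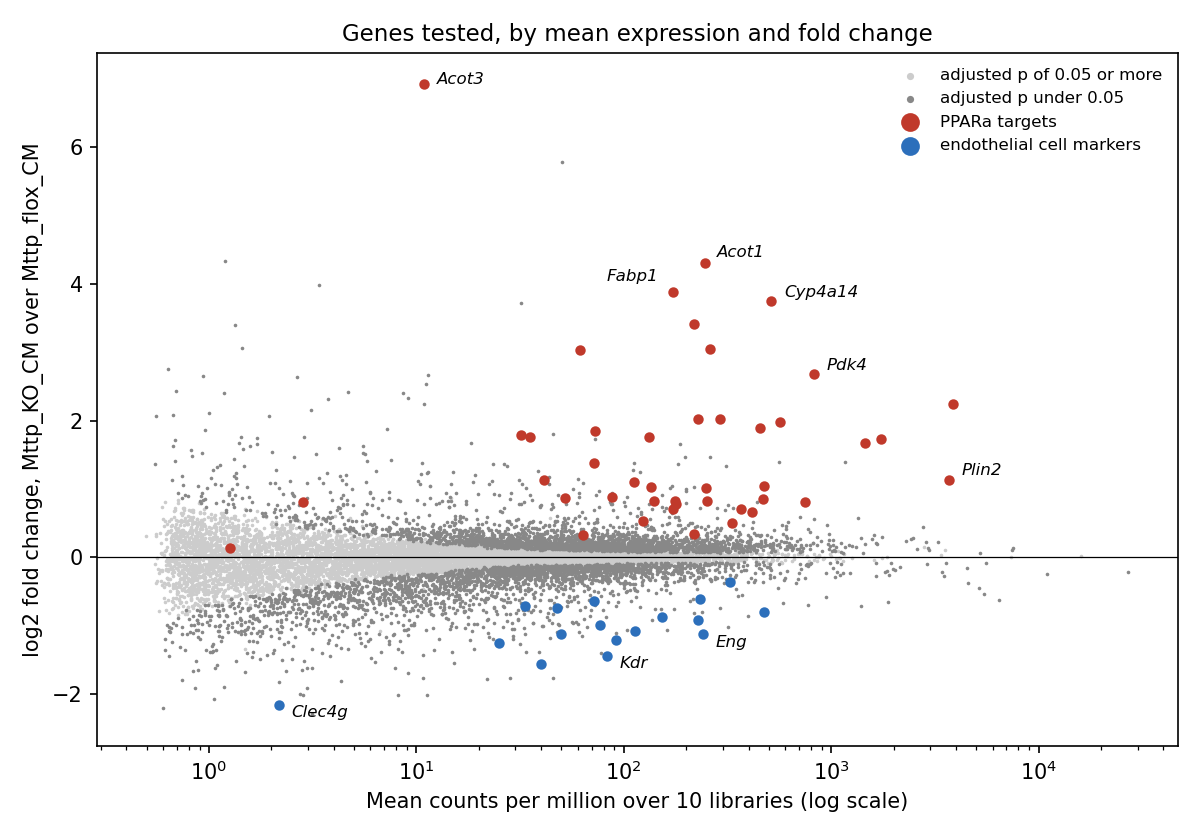
Log2 fold change of the 14183 genes tested against their mean CPM over 10 libraries (log axis), with grey tones for genes past and not past the edgeR threshold. PPARα targets (red) rise to log2 6.92 for Acot3, and the 17 endothelial markers (blue) all lie below 0.

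Hepatocyte identity genes fell in 19 of 34 and rose in 8, and adjusted over the list alone 20 fell (median log2 -0.16, camera adjusted p = 3.0e-04, and adjusted p = 0.044 with an estimated correlation). The plasma proteins Ahsg and Serpina1b fell by 0.63 and 0.71 and Apoa1 by 0.54, while Tdo2, which degrades tryptophan, rose by 0.95. Progenitor markers fell in 11 of 20 and rose in 4, Krt23, Tubb6, Tubb2b and Tmsb10, and adjusted over the list alone in 5 (median log2 -0.13, camera adjusted p = 0.027, and adjusted p = 0.26 with an estimated correlation). Their mean was 0.00, above the median because Krt23 rose by 2.65, from 0.719 CPM, and the test gave the direction of the median. Cholangiocyte markers fell in 4 of 10, Spp1, Cldn4, Sox9 and Bicc1, and 0 rose (median log2 -0.17, camera adjusted p = 0.017, and adjusted p = 0.066 with an estimated correlation). Their median was -0.26 without Mttp_KO_CM replicate 2, -0.27 with no filter and -0.11 on log2 of FPKM plus 1. Adipocyte markers had 4 of 8 genes higher and 2 lower (camera adjusted p = 0.65), with the hormone-sensitive lipase Lipe and Cidea up and Pparg and Pck1 down. Neither of the 2 lymphocyte and neutrophil markers tested, Il7r and Csf3r, passed (camera adjusted p = 0.71), nor did the sole red cell gene tested, Hba-a1 (log2 -0.30, SE 0.34).

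Stress and growth lists moved in small steps. NRF2 targets rose in 15 of 24 genes and fell in 3, Gclc, Gstm1 and Gstm3, and adjusted over the list alone 16 rose (median log2 0.15, camera adjusted p = 4.3e-06, and adjusted p = 0.012 with an estimated correlation). Hmox1, the heme oxygenase, rose by 0.57, Srxn1 by 0.56 and Gclm by 0.43. Mttp_KO_CM replicate 2 stood apart for this list, with a mean log2 CPM of 7.95 where the others averaged 7.98. Unfolded protein and integrated stress genes rose in 20 of 29 and fell in 2, Herpud1 and Xbp1, adjusted over the list alone in 21 (median log2 0.13, camera adjusted p = 4.2e-06, and adjusted p = 0.064 with an estimated correlation). The stress cytokine gene Gdf15 rose by 0.58 and the chaperone Hspa5 by 0.26. Cytosolic ribosomal protein genes rose in 47 of 59, adjusted over the list alone in 48, each by little (median log2 0.17, camera adjusted p = 2.9e-15, and adjusted p = 0.12 with an estimated correlation), with Rpl6 up by 0.23 and Rps13 by 0.26. Hypoxia genes rose in 10 of 18 and fell in 2, Ndrg1 and Pfkfb3, and 3 fell adjusted over the list alone (median log2 0.15, camera adjusted p = 0.031, and adjusted p = 0.43 with an estimated correlation), with Hilpda up by 1.04 and Egln3 by 0.93. Without Mttp_KO_CM replicate 4 the hypoxia list had camera adjusted p = 0.0578.

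Interferon-stimulated genes fell in 18 of 31 and rose in 2, Rsad2 and Iigp1, and 19 fell adjusted over the list alone (median log2 -0.24, camera adjusted p = 1.4e-04, and adjusted p = 0.32 with an estimated correlation). Ifit2 and Ifit3 fell by 1.00 and 0.98. Mttp_KO_CM replicate 3 stood apart from its group, with a mean log2 CPM of 4.76 over the list where the others averaged 4.89. Endothelial, stellate cell and macrophage markers fell in the same libraries, with medians of -0.99, -1.04 and -0.55, beside the falls of the interferon and cell cycle lists. Cell cycle genes fell in 10 of 28 and rose in 2, Mcm6 and the cell cycle inhibitor Cdkn1a (median log2 -0.19, camera adjusted p = 0.0405, and adjusted p = 0.595 with an estimated correlation). Mki67 fell by 0.62 and Top2a by 0.48. Without Mttp_flox_CM replicate 1 or 4, or Mttp_KO_CM replicate 1 or the unnumbered one, the cell cycle list had camera adjusted p = 0.0564, 0.131, 0.113 and 0.0765, 0.0700 without both unnumbered libraries and 0.0623 with a block on replicate number. Glucocorticoid receptor targets fell in 9 of 18 and rose in 3, Angptl4, Klf9 and Cdkn1a, and 4 rose adjusted over the list alone (median log2 -0.11, camera adjusted p = 0.046, and adjusted p = 0.31 with an estimated correlation). Fkbp5 fell by 0.47 and Sgk1 by 0.40. Without Mttp_flox_CM replicate 4, or Mttp_KO_CM replicate 1 or 2, the glucocorticoid list had camera adjusted p = 0.0750, 0.0594 and 0.0599, and its median was -0.17 without Mttp_flox_CM replicate 1 and -0.18 without Mttp_KO_CM replicate 3.

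The remaining lists did not pass as groups. Acute phase genes had 13 of 26 lower and 5 higher, and 8 higher adjusted over the list alone (camera adjusted p = 0.21), with fibrinogen Fgb down (log2 -0.28) and hepcidin Hamp down (log2 -0.29). Inflammatory cytokine and NF-kB genes had 10 of 23 higher and 5 lower, adjusted over the list alone 11 and 6 (camera adjusted p = 0.15), with Ptgs2, the inducible cyclooxygenase, up by 2.33 from 3.00 ± 0.758 CPM and the adhesion molecule Vcam1 down (log2 -0.97). Drug metabolism genes had 4 of 23 higher and 5 lower (camera adjusted p = 0.93), with Por up by 0.37 and Cyp2b10 down (log2 -0.80). Circadian genes had 3 of 18 higher and 6 lower, adjusted over the list alone 4 and 7 (camera adjusted p = 0.50), with Nr1d2 up by 0.29 and Cry1 down (log2 -0.28). Immediate early genes had 5 of 17 higher and 3 lower, with Klf4 up by 1.21 and Egr1 down (log2 -0.36), and their median of -0.03 and mean of 0.06 differed in sign, the test following the mean (camera adjusted p = 0.708).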

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

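The tests in this part were chosen only after the results were seen, except the test of a trend with GC content and gene length and the count of other splits of the libraries. The SE of a list median was obtained by resampling the genes of the list and not the libraries. It treats these genes as independent, so it does not measure the spread between libraries and can be too small where genes vary together.

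PPARα targets were higher in Mttp_KO_CM with a median log2 change of 1.13. The lowest median over 4 scalings was 1.09 (SE 0.284). These scalings barely differed, with a median of all genes of -0.04 at library size alone, so they could not bring the list median near 0. The values show only that the choice among these scalings did not produce the rise. A trend with GC content, gene length and expression was argued against, since removing it left 1.07 (SE 0.277). A higher share of hepatocytes was argued against too as the source of this rise, as the hepatocyte identity genes had a median of -0.16 (SE 0.0594). This does not show that the share of hepatocytes was the same in the 2 groups. The difference that the design names is the medium, and more PPARα activity in cells given knockout medium may be put forward as a hypothesis, found and tested on the same data.

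Endothelial, stellate cell and macrophage markers were lower in Mttp_KO_CM. The endothelial median nearest to 0 over 4 scalings was -0.99 (SE 0.122), and those of stellate cell and macrophage markers were -1.04 (SE 0.283) and -0.55 (SE 0.107). The scalings barely differed, so this shows only that the choice among them did not produce the falls. Removing the GC and length trend left -0.96 (SE 0.129) for endothelium. The endothelial markers ran from -2.16 to -0.36, with an SD between markers of 0.316 beyond their errors, which decides nothing about a uniform loss of non-hepatocyte cells, since no table measures the baseline that the remaining cells give each marker. Uniform or unequal loss of cells and a response of these cells to the medium may each contribute and cannot be told apart. All 17 endothelial genes, 13 of 15 stellate genes and 17 of 20 macrophage genes fell.

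Many genes passed with small changes. A library deposited more than once was argued against, since the lowest ratio of observed to counting variance over 20 pairs within a group was 1.65 (SE 0.0188), with the top 1% of genes left out. A culture or preparation batch shared by the libraries of a group cannot be told apart from the medium, because the number of samples whose characteristics give a batch, date or plate was 0. No label names such a batch, and it could add to small changes of this kind.

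Other splits of the 10 libraries into 5 and 5 were counted, 100 of the 126 possible, drawn with a fixed seed. For the genes higher, the genes lower and the median of the PPARα targets, 1 split, the real one, gave a result as large, the fewest that 100 splits can give. Any steady difference between the groups, a shared batch included, would give this, so it does not point to the medium. The real split gave 2585 genes higher and 2571 lower, and no other split gave more than 1 gene in either direction. Every other split mixes the groups, so a difference between them adds to the spread within each arm. The real PPARα median was 1.13 in size and the highest other 0.69. The PPARα list passed camera in all 100 splits, with adjusted p at most 0.0150, so its camera p alone does not set the real split apart. For the number of other lists passed, 1 split, the real one, gave as many, with 24 against 23 in the highest other, so this count barely separates the real split from those with 1 library moved.

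Some libraries stood apart from the other 4 of their group by Dixon's test at a critical value of 0.71, which chance gives for about 5% of groups. They were 17 of 456 groups tested, or 3.73%. Fabp1 was at 28.3 CPM in Mttp_flox_CM replicate 1, where the others averaged 20.3, and Prelp was at 6.77 CPM there, where the others averaged 9.99. In the unnumbered Mttp_flox_CM library Sox18 was at 18.7 CPM (highest of the others 16.2), Acsl1 at 123 CPM (others 113) and Pfkfb1 at 21.5 CPM (others 18.8). In Mttp_flox_CM replicate 3 Atp5a1 was at 727 CPM (others 747), Plin3 at 133 CPM (others 140.2) and Cxcl10 at 9.80 CPM (others 5.87). Gdf15 was at 50.004 CPM in Mttp_flox_CM replicate 2 (others 45.7) and at 77.1 CPM in Mttp_KO_CM replicate 1 (others 67.4), where Acta2 was at 1.71 CPM (others 1.12). Fgf21 was at 4.70 CPM in Mttp_KO_CM replicate 2 (others 3.35) and Fn1 at 1369 CPM in Mttp_KO_CM replicate 3 (others 1492). In the unnumbered Mttp_KO_CM library mt-Nd1 was at 3252 CPM (others 3582). The mean log2 CPM of a list stood apart for glycolysis in Mttp_flox_CM replicate 4 (6.42, others 6.18), interferon-stimulated genes in Mttp_KO_CM replicate 3 (4.76, others 4.89) and NRF2 targets in Mttp_KO_CM replicate 2 (7.95, others 7.98).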

How the results depend on the processing

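Leaving out the unnumbered libraries, robust estimation and lists without PPARα targets were chosen only after the results were seen. Mttp stayed higher under all alternatives run (log2 0.55 to 0.61), and the PPARα targets passed under all of theirs (median 1.06 to 1.15). The counts of genes stayed within 1.5 times, between 1936 and 2617 higher and between 1876 and 3217 lower, except at a fold change of at least 1.5, where 344 were higher and 716 lower because small changes no longer counted. At an adjusted p under 0.01 they were 1936 and 1876, with robust estimation 2617 and 2590, and with library size alone 1982 and 3217. Leaving out each library in turn gave 2305 to 2491 higher and 2411 to 2521 lower. With the replicate block, on the 8 numbered libraries, 2326 were higher and 2325 lower, and 2264 and 2307 without the block. For each library the deviations of log2 CPM from the group mean were taken. Between the libraries of the 4 numbered pairs, correlations of these deviations ran from -0.00887 to 0.0747, and 4 of 8 libraries matched their own number best. So few libraries do not settle whether the numbers mark pairs, and the main model used no pairing. Scaling moved the median of all genes by at most -0.04. Of the other lists 24 passed, but 12 with an estimated correlation, which widens the error of lists whose genes vary together, and 21 to 27 under the rest. Of 4742 values for 190 single genes, 4681 kept direction and call, 61 in 8 genes lost the call and 0 reversed. Of 663 values for 35 lists, 628 were kept, 27 lost the call, 8 gained it and 0 reversed. Fry also called lipoprotein assembly (adjusted p = 0.0140), gluconeogenesis (4.6e-04), acute phase (0.0397) and inflammatory genes (0.00289), and did not call the cell cycle (0.0776). With the replicate block cholesterol synthesis gained its call (camera adjusted p = 0.0331) and the cell cycle lost it (0.0623). On log2 of FPKM plus 1 the hypoxia (0.0653), glucocorticoid (0.0653) and progenitor lists (0.0690) lost theirs. On simulated data at this depth edgeR found 76% of genes changed 1.5-fold. Far fewer genes were changed there than were called here, so this does not give the power in the data. Smaller changes that were not called are not shown to be absent.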

Other observations

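The test of the PPARγ hypothesis in this part and the genes named here were chosen only after the results were seen. Txnip, a thioredoxin-binding protein that also restrains glucose uptake, rose from 89.3 ± 7.49 to 283 ± 15.3 CPM (SD, n = 5, log2 1.66, SE 0.046, edgeR adjusted p = 2.0e-19). Gm15441, a long noncoding RNA on its opposite strand, rose from 1.78 ± 0.594 to 98.6 ± 10.1 CPM (log2 5.79, SE 0.11). The genes overlap and the strand setting of the counts is not given in the sources used here, so their changes were not fully separated. A constant share of Txnip reads counted for Gm15441 could raise Gm15441 by no more than Txnip rose. The log2 changes of 5.79 and 1.66 argue against that as the whole source of the rise of Gm15441. How much reads of Gm15441 added to the rise of Txnip was not separated. Acnat2, an acyl-CoA to amino acid transferase gene, fell by 1.27 on the log2 scale, from 44.7 ± 5.30 to 18.5 ± 1.81 CPM. The glucose transporter gene Slc2a2 fell by 0.81. The chemokine genes Cxcl10 and Cxcl2 rose by 1.24 and 1.12, from 6.65 ± 1.77 and 6.43 ± 0.522 CPM.

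Xist, the noncoding RNA of the inactive X chromosome, lay between 919 and 1086 CPM in all 10 libraries and did not pass between the groups (log2 0.04, SE 0.034, edgeR adjusted p = 0.333). The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in each library. The labels give male sex for the fat donors.

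Rosiglitazone, a PPARγ ligand, was in the differentiation medium of both groups of adipocytes. More PPARγ ligand in the knockout medium may be a candidate explanation for the rise of Cidec and Ucp2. Cidec is also on the PPARα list, so it is not among the genes tested next. Ucp2 is among them, so its rise counts toward a hypothesis that it prompted. The PPARγ-linked genes that are not on the PPARα list had a median log2 change of 0.17 (SE 0.207, from resampling these genes and not the libraries). Of these 12 genes 7 were higher and 3 lower (camera adjusted p = 0.0493). The spread of the median over genes reaches below 0, so this cannot be told apart from no such effect. Pparg itself fell by 0.72.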
